A study of Arabidopsis thaliana with 6 samples.

How the data were processed

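The series measured RNA from young rosette leaves of wild type Col-0 and of 35S:AtMYB102-SRDX plants on 6 Agilent Arabidopsis arrays, 3 from control medium and 3 from medium with 200 mM NaCl. Per the labels, Cy3 carried wild type and Cy5 the transgenic plant on every array, and no array had the dyes exchanged. The groups were taken from the labels.

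Per the file headers, the arrays were read with Agilent Feature Extraction 9.1.3.1, and the deposited mean and background signals are intensity values, the brightness of each spot and its surroundings. Per the file headers, the processed signals are intensity values after background and spatial detrending and a dye normalization with linear and LOWESS steps. The deposited log ratio of each array file is the log10 of the processed Cy5 over Cy3 signals, per the file headers. The deposited series table holds log2 ratios of Cy5 over Cy3, a scale found from its values: on bright spots it correlated with the arrays' own log ratios at 0.964 to 0.990 across genes, which are not independent replicates, and at 0.289 to 0.548 over all probes. How that table was normalized is not given in the sources used here.

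Mean signals were background corrected with limma's normexp (offset 50) and normalized by loess within each array, with control spots and spots marked as outliers at weight 0. Each array holds 37685 gene spots and 1417 control spots, and 55 to 113 outlier spots per array were left out. No gene spot was saturated. Spots of a probe were averaged to 37478 probes, of which 26236 carry an Arabidopsis locus name and 11242, left out, do not. Symbols came from the RefSeq gene table of assembly TAIR10.1, which matched 26019 of these probes and not 217. The brightest probe stood for each of 25665 loci, 541 of which had several. Of 421 loci with several bright probes, 13 had control log2 ratios more than 1 apart. Genes were kept when well above background on all 3 arrays of a condition in at least 1 channel (19610), and 71 with fewer than 2 unmarked arrays in a condition were left out, so that 19539 were tested, 8688 of them with a symbol.

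The tests were made in R 4.3.3 with limma 3.58.1, data.table (version 1.17.8) and statmod 1.5.0. The genotype effects in control and in salt, their difference (the interaction) and their mean were tested on log2 ratios with lmFit and eBayes, two-sided, with 1 coefficient per condition. The salt effects within a genotype were tested with a separate-channel fit after Aquantile normalization on 19397 genes with values on all arrays (intraspot correlation 0.111). P-values were adjusted by Benjamini and Hochberg and genes with an adjusted p under 0.05 were called. Since 1 wild-type sample per condition was counted, the salt effect in wild type is given as values, and for the transgenic plants errors and adjusted p come from a limma fit of the Cy5 values alone. Where a group was not above background on any array, fold changes are given as limits against the floor of its channel.

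The 23 gene lists hold 459 genes, of which 424 were tested. They are osmotic and ABA responsive effector genes, ABA metabolism and signalling, ion transport and salt tolerance, proline and raffinose metabolism, jasmonate and wounding, jasmonate and ethylene defence, salicylic acid and pathogen defence, stress responsive transcription factors, R2R3-MYB factors, cuticle, wax and suberin, photosynthesis, phenylpropanoids and flavonoids, senescence, oxidative stress, heat shock, cell cycle, cell wall loosening, aquaporins, glucosinolates, the circadian clock, markers of root, markers of shoot apex and flower, and reference genes. List shifts were tested with limma's camera with its preset correlation, adjusted over the 23 lists of a comparison, and again with an estimated correlation and with fry. For salt in wild type, the median of a list was ranked among 10000 random lists of its size matched on signal in 20 bins.

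The comparisons, lists, tests, the other settings to try and the rule for named genes were fixed before the data were examined. By that rule, the text names MYB102, then per comparison from the 10 highest and 10 lowest called genes with a symbol and the same sign on every array (for salt effects, no overlap between conditions), from up to 3 called genes per list, or the 2 of smallest p in a list without calls, and from the clock and reference genes. Which of the allowed genes are named was chosen with their values known. Of genes in 2 groups of 3 arrays, 10% would separate without overlap by chance.

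Alternatives were no background correction, normexp without offset, the scanner's processed signals, median centring in place of loess, scale normalization between arrays, quantile normalization of all channels, median centring of each channel, a fit of 1 channel alone, no filter or a stricter filter on dim probes, the mean over probes, saturated spots left out, eBayes with trend and robust settings, the arrays of 1 condition alone, slide as a random block, replicate number as a block, a minimum log2 fold change of 1, the deposited series table, and each array left out in turn. Counting wild type as 1 sample, and leaving out both arrays numbered 3, were chosen after seeing the data.

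The tests were tried on simulated data of 19397 genes with 100 genes changed 2-fold and 100 changed 4-fold. Recovered were 74% and 96% of them for the genotype effect in control, 76% and 96% for that in salt, 43% and 88% for the interaction, 85% and 98% for the mean genotype effect, 78% and 96% for salt in wild type and 81% and 95% for salt in the transgenic plants (68% and 95% on the Cy5 values alone). The simulations of salt effects gave both channels the mean variance of Cy3 and Cy5, which is below that of Cy5. Recovery for salt in the transgenic plants may therefore be overstated. With wild type as 1 sample, 2% and 70% were recovered for the genotype effect in control. In simulated interaction data, a list of 20 genes was shifted by 1 (log2). Its adjusted p was 2.00e-28 by camera, 0.00562 with an estimated correlation and 0.00180 by fry. Camera called 1 of 22 lists that were not shifted. The simulated genes varied independently, while the osmotic list had an estimated correlation of 0.74 in the real interaction. How these tests fare on correlated lists was therefore not tested by the simulation.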

Results

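Transcript levels were measured in rosette leaves of Arabidopsis thaliana wild type Col-0 and of plants carrying 35S:AtMYB102-SRDX. This transgene drives MYB102, an R2R3-MYB transcription factor of wounding and osmotic stress, as a fusion with SRDX, a short repression domain of the EAR type. Per the labels, 3-week-old plants were moved to MS medium, or to MS medium with 200 mM NaCl, for 24 h. The series holds 6 arrays, 3 per condition, each labelled as a biological replicate. Every array carried wild type in Cy3 and the transgenic plant in Cy5, both from the same condition. Of the gene spots, 55.6% to 58.2% were well above background in Cy3 and 58.0% to 62.0% in Cy5, with median signals of 79.2 to 90.4 and 128 to 142. The number of arrays limits the precision.

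The 3 wild-type channels of a condition differed little. Their median SD over 17397 genes was 0.044 (log2) in control and 0.057 in salt. Repeated spots of 1 probe on 1 array had a median SD of 0.16 to 0.20, and the transgenic channels one of 0.16 and 0.23 between arrays. Whether the arrays of a condition carried the same wild-type RNA is not given by the labels and is not settled by these values. As a precaution wild type was counted as 1 sample per condition, in which case adjusted p-values against wild type leave out the spread between wild-type plants, and for each such comparison the count with wild type as 1 sample is given as well. Log2 fold changes are given ± SE from limma with n = 3 arrays per condition, and log2 ratios are transgenic over wild type. For ratios, limma took 1 spread per gene from the arrays of both conditions together, so that an SE does not show the spread of a single condition.

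MYB102 (AT4G21440), the gene of the transgene, was higher in the transgenic channel on every array. Its log2 ratio was 5.02, 4.83 and 2.96 on control arrays 1, 2 and 3 and 6.27, 5.96 and 4.85 on salt arrays 1, 2 and 3. The probe of SUP (AT3G23130), the floral zinc finger gene from which the repression domain was taken, had log2 ratios of 7.80, 7.63 and 6.02 in control and 8.71, 8.48 and 7.38 in salt. Over the control arrays these are 4.27 ± 0.46 (adjusted p = 0.00240) and 7.15 ± 0.41, with the SUP probe above background in wild type on 2 of the 3. Both ratios were lowest on the array numbered 3 of each condition.

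**Figure D1:**
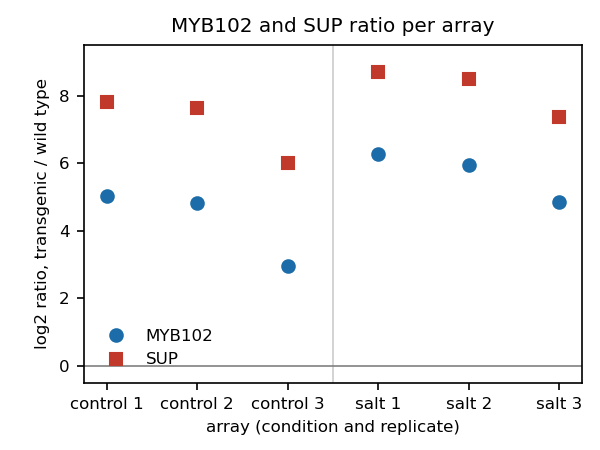
Log2 ratio of transgenic over wild type for MYB102 (circles) and SUP (squares) on each of the 6 arrays, with arrays on the horizontal axis. MYB102 lies between 2.96 and 6.27 and SUP between 6.02 and 8.71.

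The first comparison asks how the transgenic leaves differed from wild type on control medium. FMO1, a monooxygenase of systemic acquired resistance, had a log2 ratio of -7.45 ± 0.44 (adjusted p = 0.000459), ICS1, which makes the precursor of salicylic acid, -4.50 ± 0.32 and the glutaredoxin gene GRX480 -4.60 ± 0.98. Lower as well were EM1 (-4.78 ± 0.90) and LEA7 (-4.75 ± 0.71), which encode LEA proteins of drying tissue, and the ABA-responsive RD29B (-4.04 ± 0.32). On the higher side stood the expansin genes EXPA8 (3.46 ± 0.26) and EXPA1 (3.27 ± 0.15), whose products loosen cell walls, and the water channel genes PIP2-3 (2.24 ± 0.17), TIP1-2 (1.75 ± 0.19) and PIP2-2 (1.57 ± 0.18).

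Of the 26 salicylic acid and defence genes measured, 20 were lower and 0 higher (21 lower when adjusted over the list alone), with a median of -2.56. The osmotic and ABA responsive effector genes had 14 of 22 lower and 0 higher (14 lower adjusted over the list alone), median -1.68. Among stress responsive transcription factors, 8 of 29 were lower and 0 higher (7 lower adjusted over the list alone), led by the zinc finger genes ZAT7 (-4.52 ± 0.51) and ZAT12 (-3.94 ± 0.68). In the jasmonate and wounding list, 10 of 24 genes were lower and 1 higher, the same counts adjusted over the list alone. They included the lipoxygenase genes LOX4 (-2.58 ± 0.60) and LOX3 (-1.79 ± 0.43) and the aminotransferase gene TAT3 (-2.09 ± 0.60). The median of this list was -0.44, but 0.48 with median centring in place of loess, where the median of all genes was 0.77. Phenylpropanoid and flavonoid genes were lower in 5 of 23 cases and higher in 1 (11 lower and 1 higher adjusted over the list alone), with F3H at -1.49 ± 0.45 and TT19 at -1.80 ± 0.54. Aquaporin genes were higher in 12 of 17 cases and lower in 0, the same counts adjusted over the list alone, with a median of 0.96. Of 20 cell cycle genes, 6 were higher (0 adjusted over the list alone) and 0 lower, among them the B-type cyclin genes CYCB1-2 (1.18 ± 0.35) and CYCB2-2 (0.99 ± 0.24). These 7 lists passed limma's camera with its preset correlation, with adjusted p from 1.76e-09 for salicylic acid genes to 0.0307 for flavonoid genes. None passed with the correlation estimated from the data (adjusted p = 0.783 with an estimated correlation for each of the 7). The flavonoid list missed the preset test without control replicate 3 (camera adjusted p = 0.236) and without salt replicate 1 (camera adjusted p = 0.0545).

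Single genes outside these groups included MT1C, a metallothionein gene, at 3.03 ± 0.20, the cytochrome P450 gene CYP81D11 at 3.25 ± 0.47 and the catalase gene CAT2 at 2.49 ± 0.16. Lower were DMP1 (-6.76 ± 0.48), the transcription factor genes BHLH92 (-6.45 ± 0.67), ZAT11 (-6.07 ± 0.55) and MYB15 (-4.76 ± 0.53), the defence-related YLS9 (-5.58 ± 0.23) and ERF1 (-3.09 ± 0.55), an ethylene response factor gene. Photosynthesis genes went both ways, with 13 of 33 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.0836). The Rubisco gene RBCS2B (1.85 ± 0.39) and the Rubisco activase gene RCA (1.59 ± 0.22) were among the higher ones. In the ion transport list, 8 of 21 genes were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.193), with the calcium exchanger gene CAX1 at 1.36 ± 0.19 and the proton pump gene AHA2 at 1.26 ± 0.11.

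By limma on the ratios, 7612 of 19539 genes differed in control, 3876 higher and 3736 lower. With the scanner's processed signals, which moved the median of all genes to 0.21, the split was 6151 to 2370, and with median centring 13908 to 1032. Counting wild type as 1 sample left 226 genes, 57 higher and 169 lower, among them 10 of the 36 named here (CAT2, DMP1, EXPA1, EXPA8, FMO1, ICS1, MT1C, RCA, SUP and YLS9). On simulated arrays that carried 1 wild-type RNA as variable as the transgenic ones, the ratio test called 1060 unchanged genes out of 19397. They made up 85.1% of its calls, a share that depends on only 100 genes having been changed 2-fold and 100 changed 4-fold. This share cannot be carried over to the real calls. The count was 2721 without control replicate 2 and 3310 without control replicate 3. Of the 36 genes named for this comparison, 24 passed without either of these arrays, and the 12 that missed the threshold were CYCB1-2, CYCB2-2, EM1, ERF1, F3H, GRX480, LOX3, LOX4, RBCS2B, TAT3, TT19 and ZAT12. No array had the dyes exchanged, so that dye and genotype cannot be told apart within a condition.

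Under salt, the question is the same at 200 mM NaCl. CBF3, a transcription factor gene of the cold and drought response, had a log2 ratio of 4.49 ± 0.83 (adjusted p = 0.0204) and SWEET15, a sugar transporter gene of ageing leaves, 4.48 ± 0.52. The morning clock gene CCA1 was at 4.22 ± 0.53, BSMT1, a methyltransferase gene of benzoic and salicylic acid, at 4.06 ± 0.37 and the B-box gene BBX31 at 4.06 ± 0.56. Over the salt arrays alone, the SDs of these log2 ratios were 2.16 for CBF3, 0.75 for SWEET15, 1.39 for CCA1, 0.95 for BSMT1 and 1.61 for BBX31. MYB102 itself was at 5.69 ± 0.46 and SUP at 8.19 ± 0.41. Lower genes included the glycosyltransferase gene UGT85A3 (-2.50 ± 0.38), the glutathione transferase gene GSTU20 (-1.90 ± 0.26) and BCAT4 (-1.87 ± 0.32), which acts in methionine-derived glucosinolate synthesis.

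In the list of ABA metabolism and signalling, 11 of 33 genes were higher and 1 lower (13 and 3 adjusted over the list alone), including NCED3, which limits ABA synthesis (2.64 ± 0.53), and CYP707A1, which breaks ABA down (2.37 ± 0.57). Stress responsive transcription factors were higher in 10 of 29 cases and lower in 1 (12 and 2 adjusted over the list alone). The R2R3-MYB list had 4 of 15 higher and 0 lower (6 higher adjusted over the list alone), with MYB112 at 3.04 ± 0.25. Senescence genes were higher in 7 of 17 cases and lower in 0 (9 higher adjusted over the list alone), among them DIN2 (3.16 ± 0.34) and SRG1 (2.61 ± 0.39). Of 12 clock genes, 8 were higher and 0 lower (8 and 1 adjusted over the list alone), with PRR5 at 2.12 ± 0.17, RVE8 at 1.77 ± 0.21 and PRR7 at 1.51 ± 0.17. Lower groups were cell cycle genes, with 6 of 20 lower and 0 higher, the same adjusted over the list alone, and glucosinolate genes, with 9 of 18 lower and 1 higher, the same adjusted over the list alone. Examples are the replication genes MCM2 (-1.24 ± 0.27) and PCNA2 (-1.07 ± 0.24) and the chain elongation gene MAM1 (-1.73 ± 0.31). These 7 lists passed camera with its preset correlation (adjusted p 0.00234 to 0.00933), and none passed with an estimated one, with adjusted p = 0.702 to 0.857 with an estimated correlation. Without salt replicate 1, the transcription factor list missed the threshold (camera adjusted p = 0.0717).

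Osmotic and ABA responsive effector genes were higher in 4 of 22 cases and lower in 0, the same adjusted over the list alone (camera adjusted p = 0.191). They included EM6 (3.58 ± 0.76), LEA7 (3.03 ± 0.71) and the dehydrin gene RAB18 (2.53 ± 0.46). In that order, the log2 ratios had SDs of 2.28, 0.65 and 0.34 over the salt arrays and 0.16, 2.03 and 1.34 over the control arrays. Jasmonate genes were lower in 7 of 24 cases and higher in 0 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0623), with AOC2 at -1.83 ± 0.28 and JAZ10 at -1.48 ± 0.15. Further genes were PBS3 (2.25 ± 0.41), which acts in salicylic acid synthesis, ELIP1 (3.82 ± 0.97), a light stress gene of the chloroplast, and FUM2 (-1.84 ± 0.21), which encodes cytosolic fumarase. Their SDs over the salt arrays were 1.21, 2.71 and 0.47 in that order. CAT2 (1.57 ± 0.16), EXPA1 (1.71 ± 0.15) and PIP2-3 (1.25 ± 0.17) were higher here as in control.

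By limma on the ratios, 5060 of 19539 genes differed under salt, 2873 higher and 2187 lower. The ratios of salt replicate 3 stood apart. They correlated across genes at 0.43 and 0.58 with salt replicates 1 and 2, which correlated at 0.86 with each other. With the control arrays, salt replicate 3 correlated at 0.17 to 0.20, and salt replicates 1 and 2 at -0.33 to -0.11. With the scanner's processed signals (median of all genes 0.18) the split was 4413 to 863, and with median centring (0.57) 12150 to 410. With wild type as 1 sample limma called 0 genes, while 2146 had an unadjusted p under 0.05, and a limma fit of the 3 salt arrays alone also called 0, with 6430 at an unadjusted p under 0.05. The count was 3 without salt replicate 2, so that none of the 36 genes named for this comparison passed without that array. It was 1476 without salt replicate 1 (25 of the 36 passed), 1139 without control replicate 2 (26 passed), 3320 without control replicate 1 and 3306 without control replicate 3 (32 passed for each). Genes that missed the threshold in more than 1 of these cases include CBF3, CYP707A1, ELIP1, LEA7, MCM2, PBS3 and PCNA2.

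**Figure D2:**
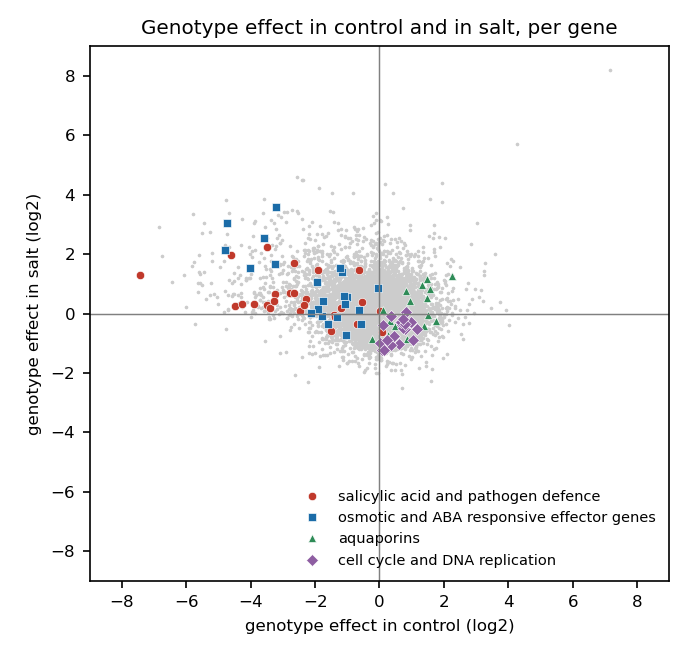
Each point is 1 gene, with its log2 ratio of transgenic over wild type in control on the horizontal axis and in salt on the vertical axis, and 4 gene lists coloured. Salicylic acid genes have a median of -2.56 in control and 0.32 in salt, and aquaporin genes one of 0.96 and 0.13.

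The interaction compares the ratios of the salt arrays with those of the control arrays, which removes any dye effect common to all arrays. FMO1 had a log2 ratio 8.74 ± 0.63 higher in salt than in control (adjusted p = 0.00183). The same direction was taken by DMP1 (8.71 ± 0.68), ELIP1 (8.58 ± 1.37), LEA7 (7.78 ± 1.01) and the B-box gene BBX29 (7.42 ± 0.86). Among genes of ABA and salt responses, EM1 was at 6.94 ± 1.27, NCED3 at 3.36 ± 0.76 and P5CS1, which makes proline, at 2.43 ± 0.48. The other direction was taken by BCAT4 (-3.50 ± 0.45), the cell wall gene XTH31 (-3.12 ± 0.25) and the nitrilase gene NIT2 (-2.92 ± 0.47). MYB102 itself differed by 1.42 ± 0.65, which did not pass (adjusted p = 0.129).

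In 11 lists the interaction passed camera with its preset correlation, and none of the 11 passed with the correlation estimated from the data (adjusted p = 0.674 to 0.796 with an estimated correlation). Positive shifts were those of salicylic acid genes (20 of 26 higher, 1 lower; 22 and 1 adjusted over the list alone), osmotic effector genes (14 of 22 higher, 0 lower; 15 higher adjusted over the list alone) and stress transcription factors (15 of 29 higher, 0 lower; 17 and 1 adjusted over the list alone). Examples are PBS3 (5.75 ± 0.58), CBF3 (6.90 ± 1.18) and ZAT12 (5.86 ± 0.96). ABA genes had 15 of 33 higher and 1 lower (18 and 1 adjusted over the list alone). R2R3-MYB genes had 6 of 15 higher and 0 lower, the same adjusted over the list alone, with MYB15 at 4.23 ± 0.75 and MYB112 at 3.21 ± 0.35. Clock genes had 7 of 12 higher and 0 lower (8 higher adjusted over the list alone), with CCA1 at 6.09 ± 0.74 and RVE8 at 2.35 ± 0.30.

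Negative shifts were those of cell cycle genes, with 13 of 20 lower and 0 higher (17 lower adjusted over the list alone), and of photosynthesis genes, with 13 of 33 lower and 3 higher (14 and 3 adjusted over the list alone). Their examples are KNOLLE, a syntaxin gene of cell division (-1.95 ± 0.51), PCNA1 (-1.64 ± 0.46) and RBCS2B (-2.64 ± 0.55). The cell wall loosening list had 7 of 12 lower and 0 higher, the same adjusted over the list alone, with EXPA10 at -2.53 ± 0.41 and EXPA11 at -1.91 ± 0.29. Aquaporin genes had 7 of 17 lower and 0 higher (10 lower adjusted over the list alone), with TIP1-2 at -2.01 ± 0.27 and PIP1-5 at -1.70 ± 0.23. Glucosinolate genes had 8 of 18 lower and 3 higher (9 and 3 adjusted over the list alone), with CYP79F1 at -2.87 ± 0.41. Camera's adjusted p ran from 4.11e-08 for salicylic acid genes to 0.0185 for photosynthesis genes. The photosynthesis list missed the preset test without salt replicate 1 (camera adjusted p = 0.262) and with the scanner's processed signals (camera adjusted p = 0.127).

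By limma on the ratios, the interaction passed for 6771 of 19539 genes, 3623 higher in salt and 3148 lower. Median centring, which moved the median of all genes to -0.17, turned this split to 1875 and 5231. In 5350 of them the log2 ratio had opposite signs in the 2 conditions. Ageing-related SWEET15 (6.86 ± 0.74) and NAP (3.64 ± 0.45) were among the called genes. Genes called in both conditions numbered 1931, of which 1266 had the same sign and 665 opposite signs, and independent lists of these sizes would share 1971. With wild type as 1 sample, 39 genes passed, all higher, and none of the 32 called genes named here was among them (lowest adjusted p = 0.0921, FMO1). The count was 874 without control replicate 2, 2330 without control replicate 3 and 1267 without salt replicate 2, and of the 32 called genes named for this comparison 18, 26 and 23 passed. EM1, FUL, KNOLLE, NCED3, PCNA1 and RBCS2B missed the threshold in each of these 3 cases, and CBF3, MYB15 and P5CS1 without control replicate 2 and without salt replicate 2. The control arrays were on 1 slide and the salt arrays on another, so that slide and condition cannot be told apart.

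**Figure D3:**
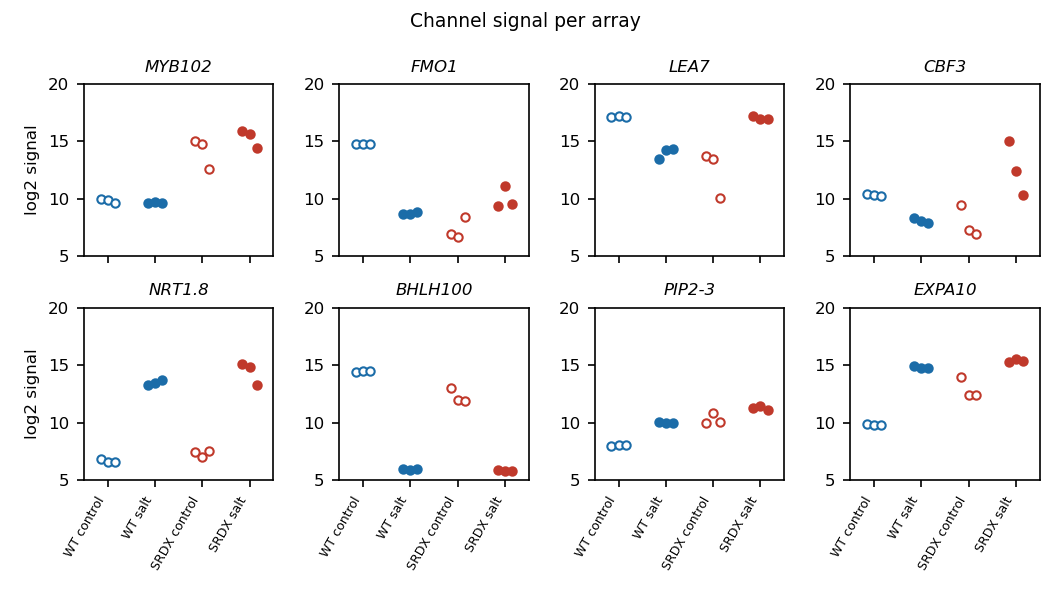
Log2 signal of 8 genes in each channel of each array, with the 4 groups on the horizontal axis, wild type in blue, 35S:AtMYB102-SRDX in red, control as open and salt as filled circles. Wild-type FMO1 is highest on control medium, while NRT1.8 rises and BHLH100 falls with salt in both genotypes.

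The mean genotype effect averages the difference from wild type over both conditions. Cy5 carried the transgenic plant on every array, so that dye and genotype cannot be told apart in this mean. MYB102 was higher by 4.98 ± 0.32, and MT1C (3.03 ± 0.14), EXPA1 (2.49 ± 0.11) and CAT2 (2.03 ± 0.11) were higher on all 6 arrays. So were the aquaporin genes PIP2-3 (1.75 ± 0.12) and TIP2-2 (1.32 ± 0.13) and the potassium channel gene KAT1 (1.27 ± 0.18). Lower were EXO (-2.34 ± 0.39), ERF2 (-1.52 ± 0.11), an ethylene response factor gene, and OPR3 (-1.09 ± 0.081), which acts in jasmonate synthesis. The wax synthesis gene CER3 was higher by 0.67 ± 0.065.

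Aquaporin genes were higher in 10 of 17 cases and lower in 1, the same adjusted over the list alone. Salicylic acid genes were lower in 14 of 26 cases and higher in 0 (16 lower adjusted over the list alone), with FMO1 at -3.08 ± 0.31 and ICS1 at -2.12 ± 0.23, both lower in control and not in salt. Jasmonate genes were lower in 11 of 24 cases and higher in 0, the same adjusted over the list alone, with TAT3 at -1.73 ± 0.43. Osmotic effector genes were lower in 7 of 22 cases and higher in 0, the same adjusted over the list alone, with the dehydrin gene ERD14 at -0.97 ± 0.16. In salt the medians of the salicylic acid and osmotic lists were 0.32 and 0.56, so that their mean effects rest on control (-2.56 and -1.68). The aquaporin median was 0.13 in salt, with 6 genes higher and 3 lower, against 0.96 in control. The mean shift of the aquaporin list thus rests mainly on control as well. In the mean, the medians of the jasmonate and osmotic lists, -0.51 and -0.60, became 0.24 and 0.53 with median centring, which moved the median of all genes to 0.69, and ERD14 became 0.19. These 4 lists passed camera with its preset correlation (adjusted p 2.13e-06 to 0.00935) and did not pass with an estimated one (adjusted p = 0.897 with an estimated correlation for each). The osmotic list missed the preset test without control replicate 3 (camera adjusted p = 0.162) and without salt replicate 3 (camera adjusted p = 0.0802).

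In all, 7006 of 19539 genes passed by limma, 3772 higher and 3234 lower. The scanner's processed signals (median of all genes 0.19) gave 6544 and 1475, and median centring 15067 and 679. Counting wild type as 1 sample left 52 genes, 16 higher and 36 lower, among them CAT2, EXPA1 and MT1C of the 15 named here. A limma fit with 1 coefficient and slide as a random block called 0, with 2073 at an unadjusted p under 0.05. The count was 3376 without control replicate 2, 4368 without control replicate 3 and 3574 without salt replicate 2. Without each array but salt replicate 2, TAT3 missed the threshold, and the other 14 genes named here passed in each of the 6 cases.

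For the salt effect in wild type, counted as 1 sample per condition, fold changes and list medians are given without a p-value. Control and salt arrays were on different slides, so that slide and salt cannot be told apart in these values. The nitrate transporter gene NRT1.8 was higher in salt by 6.83 (log2) and NRT2.6 was at least 79.0-fold higher, since wild type in control was not above background. AGP7 (5.73), NIT2 (5.58), RAP2-6 (5.47), an ethylene response factor gene, and RNS1 (5.58), a ribonuclease gene, were higher too. The iron deficiency factors BHLH100, BHLH101 and bHLH38 were at least 302-fold, 213-fold and 152-fold lower in salt, where they were not above background. MYB102 was at -0.21.

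Salicylic acid genes were lower by at least 1 (log2) in 24 of 25 cases and higher by as much in 0, with GRX480 at -7.55, FMO1 at -6.04 and NIMIN2 at -5.42. Their median of -3.52 was at percentile 0 of 10000 random lists of the same size and signal. At percentile 0 stood also flavonoid genes (median -1.18; 15 of 23 lower by at least 1, 1 higher), jasmonate genes (median -1.09; 13 of 24 lower, 2 higher) and stress transcription factors (median -1.03; 15 of 29 lower, 5 higher). Examples are F3H (-2.16), F3PH (-2.67), TAT3 (-3.22) and LOX4 (-3.25). Jasmonate and ethylene defence genes had a median of -2.07 (percentile 0.02; 6 of 7 lower by at least 1, 0 higher), with ORA59 at -2.09. Osmotic effector genes went both ways, 6 of 22 lower by at least 1 and 6 higher (median -0.53, percentile 0.1), with EM1 at -3.87, RAB18 at -3.37 and LEA7 at -3.17. Aquaporin genes were higher by at least 1 in 11 of 17 cases and lower in 0 (median 1.38, percentile 100), with PIP2-3 at 1.96, PIP2-1 at 1.93 and TIP1-1 at 1.90. Cell wall loosening genes were at percentile 100 (median 1.19; 7 of 12 higher by at least 1, 1 lower), with EXPA10 at 4.97 and XTH24 at 3.93. The pathogen-related LURP1 (-7.29) and ECS1 (-6.82) and CYP79B3 (-2.59), which acts in indole glucosinolate synthesis, were lower. Random lists leave out the correlation between genes. With the arrays taken as independent, camera called 5 of the 23 lists with its preset correlation, 0 with an estimated one (3 at an unadjusted p under 0.05) and fry 19.

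Of 19397 genes, 1692 were higher and 2312 lower in salt by at least 1 (log2). The planned separate-channel fit called 11550 genes, a count that takes the 3 wild-type channels of a condition as independent samples. With wild type as 1 sample and the spread of the transgenic channels, limma called 1295, 549 higher and 746 lower.

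In the transgenic plants 3 arrays per condition were compared, and SE and adjusted p below come from limma on the Cy5 values alone. Slide and salt cannot be told apart here either, since control and salt arrays were on different slides. NRT1.8 rose by 7.08 ± 0.48 (log2, adjusted p = 0.000949) and NRT2.6 by 5.55 ± 0.59. The LEA gene EM6 (6.12 ± 1.26), GH3.3 (6.01 ± 0.89), which conjugates auxin, and ACS2 (5.32 ± 0.85), of ethylene synthesis, rose as well. BHLH100 and BHLH101 were at least 74.9-fold and 41.7-fold lower in salt, where they were not above background. ECS1 (-6.50 ± 0.44), LURP1 (-6.29 ± 0.59), PCC1 (-5.93 ± 0.60) and the methylesterase gene MES18 (-4.87 ± 0.23) fell. MYB102 changed by 1.21 ± 0.72, which did not pass (adjusted p = 0.210).

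Osmotic effector genes rose in 14 of 22 cases and fell in 0, with LEA7 at 4.61 ± 0.96 and LEA4-5 at 4.52 ± 0.84. ABA genes rose in 17 of 33 cases and fell in 2, with the phosphatase gene HAI3 at 4.28 ± 0.37 and CYP707A1 at 4.28 ± 0.79. Proline and raffinose genes rose in 8 of 12 cases and fell in 0; both P5CS2 (1.99 ± 0.32), of proline synthesis, and PRODH1 (2.70 ± 0.71), of its breakdown, rose. Stress transcription factors rose in 17 of 29 cases and fell in 2, with CBF3 at 4.68 ± 1.27. Senescence genes rose in 9 of 17 cases and fell in 1, with SWEET15 at 4.64 ± 0.85 and RNS1 at 3.85 ± 0.87. Clock genes rose in 10 of 12 cases and fell in 2, with CCA1 at 5.53 ± 0.72, PRR5 at 2.60 ± 0.22 and RVE8 at 2.24 ± 0.27. Cell cycle genes fell in 10 of 20 cases and rose in 0, with KNOLLE at -2.00 ± 0.51 and CYCB1-4 at -1.59 ± 0.32. Photosynthesis genes fell in 14 of 33 cases, with RBCS2B at -1.88 ± 0.38, and rose in 2, with LHCB2-1 at 2.32 ± 0.19. Glucosinolate genes fell in 10 of 18 cases and rose in 1, with CYP79B3 at -3.61 ± 0.34 and CYP83B1 at -2.57 ± 0.33.

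These 9 lists passed camera with its preset correlation on the Cy5 values, from adjusted p = 0.000474 for cell cycle genes to 0.0316 for ABA genes. None passed with the correlation estimated from the data (adjusted p = 0.674 with an estimated correlation for each of the 9). The ABA list missed the preset test without salt replicate 1 (camera adjusted p = 0.0580). In the planned separate-channel fit, their counts of higher and lower genes were 17 and 0 for osmotic, 21 and 6 for ABA, 9 and 0 for proline and raffinose, 19 and 2 for transcription factor, 11 and 1 for senescence, 10 and 2 for clock, 0 and 20 for cell cycle, 2 and 21 for photosynthesis and 1 and 13 for glucosinolate genes. Adjusted over the list alone they were 17 and 0, 22 and 7, 9 and 0, 19 and 2, 12 and 1, 10 and 2, 0 and 20, 2 and 21, and 1 and 13 in the same order. Salicylic acid genes went both ways, 8 of 25 rising and 8 falling (camera adjusted p = 0.352), with FMO1 at 2.70 ± 0.61 and WRKY54 at -4.48 ± 0.15, and the R2R3-MYB gene MYB74 rose by 4.72 ± 0.87.

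By limma on the Cy5 values alone, 8847 of 19539 genes passed, 4776 higher and 4071 lower in salt. The planned separate-channel fit, which pools in the small spread of the wild-type channels, called 12692 of 19397, 6866 higher and 5826 lower.

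**Figure D4:**
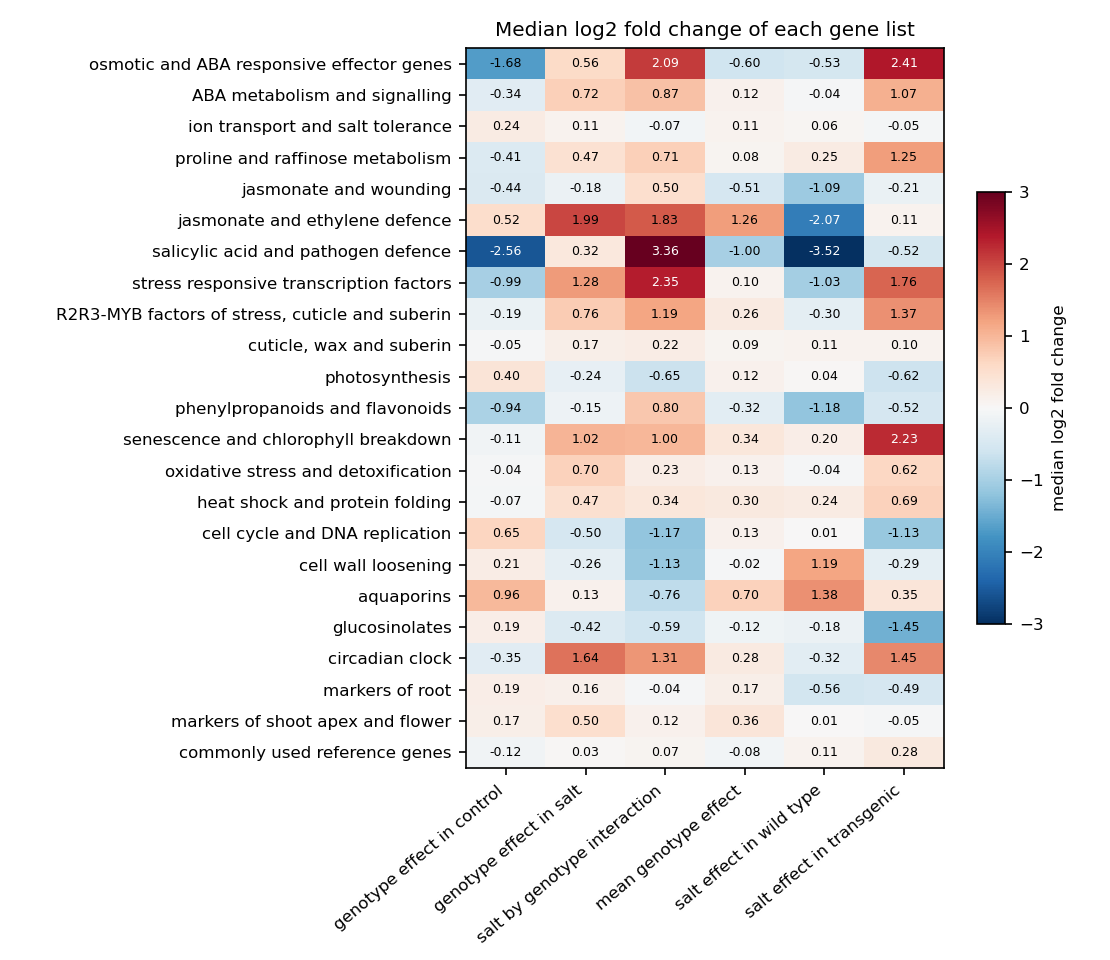
Median log2 fold change of the 23 gene lists (vertical axis) in the 6 comparisons (horizontal axis), with the value in each cell. The salicylic acid list ranges from -3.52 for salt in wild type to 3.36 for the interaction, and the reference genes lie between -0.12 and 0.28.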

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

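Of the tests below, the splits of the arrays were planned, and the tests of the 3 weighed patterns were chosen only after the result was seen. The interaction term of limma tested whether the genotype effect differed between salt and control, and every single-gene difference in this part passed it with the arrays as planned and none with wild type counted as 1 sample, while the lists were tested with camera.

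The genotype effect differed between the conditions in 6771 genes. No other of the 10 splits of the 6 arrays into 3 and 3 called any gene by limma (1615 at an unadjusted p under 0.05 in the highest), and 10 splits are too few for a share under 0.05. The median difference in log2 ratio, salt minus control, was 3.36 for salicylic acid genes, 2.35 for stress transcription factors, 2.09 for osmotic effector genes, 1.31 for clock genes, 1.19 for R2R3-MYB genes and 0.87 for ABA genes. It was -1.17 for cell cycle genes, -1.13 for cell wall loosening genes, -0.76 for aquaporin genes, -0.65 for photosynthesis genes and -0.59 for glucosinolate genes. These 11 list differences passed camera with its preset correlation and not with an estimated one (adjusted p = 0.674 to 0.796 with an estimated correlation).

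Among single genes the difference was 8.74 for FMO1, 8.71 for DMP1, 8.58 for ELIP1, 7.78 for LEA7, 7.42 for BBX29, 6.94 for EM1, 6.90 for CBF3, 6.86 for SWEET15, 6.09 for CCA1, 5.86 for ZAT12, 5.75 for PBS3 and 4.45 for UPOX. Smaller positive differences were 4.23 for MYB15, 3.64 for NAP, 3.36 for NCED3, 3.21 for MYB112, 2.43 for P5CS1, 2.35 for RVE8, 2.01 for KCS1 and 1.20 for FUL. Negative differences were -3.50 for BCAT4, -3.12 for XTH31, -2.92 for NIT2, -2.87 for CYP79F1, -2.64 for RBCS2B, -2.53 for EXPA10, -2.06 for CAX1, -2.01 for TIP1-2, -1.95 for KNOLLE, -1.91 for EXPA11, -1.70 for PIP1-5 and -1.64 for PCNA1. Of these 32 genes, 18 passed without control replicate 2, 26 without control replicate 3 and 23 without salt replicate 2, and EM1, FUL, KNOLLE, NCED3, PCNA1 and RBCS2B missed the threshold in each of these 3 cases.

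The first weighed pattern is that the genotype ratios of osmotic and salicylic acid genes turned between the conditions. A swap of the control and salt labels of the wild-type RNA is argued against by shared signs. Of the genes with a transgenic salt change of at least 2 (log2), 82.2% (909 of 1106) had the same sign in wild type. Both channels were read from the same slides, so that a slide difference common to both would raise this share too. A dye balance that differed between the slides is argued against by the spike-in probes. Their highest shift was 0.508, while the median absolute difference over the genes of both lists was 2.60. For salicylic acid genes, 24 of 26 highest in wild type in control, the state of the plants in that group may account for the turn, since it lay 2.88 above the mean of the other groups and the next group -1.74 from its own. For osmotic genes the transgenic control group lay furthest from the others (-1.84), followed by the transgenic salt group (1.32), with wild type in control at 0.70. By the criterion first used, this speaks against the same explanation. A criterion put in its place with these values known was the distance from the mean of the salt groups. It was 0.062 for wild type in control and -2.00 for the transgenic control group, which leaves that explanation open. An effect of the transgene in control cannot be told apart from it with wild type counted as 1 sample. Other lists were not weighed in this way. Genotype in control and salt in wild type share the wild-type control sample, and the aquaporin medians there were 0.96 and 1.38. They were 0.13 for genotype in salt and 0.35 for salt in the transgenic plants. For flavonoid genes the medians were -0.94, -1.18, -0.15 and -0.52 in this order. Cell cycle genes did otherwise, at 0.65, 0.014, -0.50 and -1.13.

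The second pattern is that the wild-type channels of a condition varied far less between arrays than the transgenic ones. A quieter Cy3 reading as the whole cause is argued against by spike-in probes, whose spread in Cy3 was 0.811 of that in Cy5 or more. The same wild-type RNA on every array of a condition may be the source, but the spread of wild type, at most 0.273 of the transgenic spread, is the pattern itself, so that this cannot be told apart from wild-type plants that differed little. No biological explanation was tested.

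The third pattern is that the SUP probe followed the MYB102 probe across the transgenic channels: its difference from MYB102 had the smallest SD of 19396 genes (rank 1, SD 0.12, the next gene PGDH at 0.28). The SUP probe may read the repression domain of the transgene, but this rank is the pattern itself and no other test was made. Whether the plant's own SUP gene rose with the transgene cannot be told apart from this, since there is 1 SUP probe on the array.

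For the mean genotype effect, 7006 genes passed, and 1 of 32 sign patterns of the arrays, the real one, gave as many, but with wild type counted as 1 sample the arrays of a condition do not change sign independently, and 1 sign per condition leaves too few patterns for a share under 0.05. The highest other, 6771, is the pattern that turns all salt arrays and so equals the interaction, which points to a structure of the samples by condition. For the genotype effect in control, 7612 genes passed and 0 by limma in the highest other of 4 sign patterns (319 at an unadjusted p under 0.05), with 1 pattern giving as many, and 4 patterns are too few for a share under 0.05. In salt, 5060 passed and 0 in the highest other by limma (1777 at an unadjusted p under 0.05), again too few patterns. For salt in wild type, 11550 passed and 0 in the highest other of 10 splits by limma (5 at an unadjusted p under 0.05), and for salt in the transgenic plants 12692 and 1, both with too few splits for a share under 0.05.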

How the results depend on the processing

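Counting wild type as 1 sample and leaving out the arrays numbered 3 were tests chosen only after the result was seen. Counts stayed within 1.5 times of the planned ones without background correction, without offset, with processed signals, with scale normalization, under each filter on dim probes, with the mean over probes, with trend and robust eBayes and with the series table. Median centring gave 14940 genes for control, 12560 for salt and 15746 for the mean genotype effect. With wild type as 1 sample, limma called 226, 0 (2146 at an unadjusted p under 0.05), 39 and 52 genes for control, salt, interaction and mean, 1295 for salt in wild type, and 70 of the 197 named values passed, against 194. A log2 fold change of at least 1 as well left 1901, 916, 2925 and 610 for the ratio comparisons, 3873 for salt in wild type and 4638 for salt in the transgenic plants, since fewer genes reach it. Without the arrays numbered 3, 4074 passed for control and 4544 for the mean. The salt arrays alone gave 0 genes by limma (6430 at an unadjusted p under 0.05), and slide as a random block 0 for the mean (2073 at an unadjusted p under 0.05). With an estimated correlation, camera called 0 of 43 list shifts among 138, and fry called 54, 26 of them shared. Unless the alternative means fewer samples or genes, the cause was not tested.

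Leaving out 1 array at a time gave 2721 (without control replicate 2) to 9130 genes for control, 3 (without salt replicate 2) to 7005 for salt, 874 (without control replicate 2) to 8661 for the interaction and 3376 (without control replicate 2) to 7096 for the mean. It gave 9604 to 11868 for salt in wild type, 10611 to 13439 for salt in the transgenic plants, 43 to 47 list shifts and 144 (without salt replicate 2) to 192 named values. With median centring, the direction by camera, which compares a list with the other genes, turned for markers of root, genotype effect in salt (median 0.16, then -0.0014), and for stress responsive transcription factors, mean genotype effect (median 0.10, then 0.95, with no change of sign). The medians of 3 lists that passed changed sign there while their direction by camera stayed, to 0.48 for jasmonate genes in control, 0.53 for osmotic genes in the mean and 0.24 for jasmonate genes in the mean, and ERD14, mean genotype effect, turned to 0.19. The cause was not tested.

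With replicate number as a replicate block, 6766 genes passed for the interaction, 11586 for salt in wild type and 12646 for salt in the transgenic plants. The labels do not say that the numbers pair the arrays. After subtraction of the mean of each condition, the ratios of same-numbered arrays correlated across genes at 0.21, -0.030 and 0.27, and control replicates 1 and 3 correlated best with the salt array of their own number and control replicate 2 with salt replicate 3 (0.064). Slide as a block was not run for the salt comparisons, since each slide holds 1 condition. No gene had a saturated spot, so that leaving such genes out tests nothing. In 277 of the genes called for control, 83 for salt, 721 for salt in wild type and 378 for salt in the transgenic plants, 1 group was not above background, so that their fold changes are limits.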

Other observations

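The comparison of the spread of wild type with that of the transgenic channels, and the simulation built on it, were chosen only after the result was seen, and the genes were picked among those the fixed rule allows with their values known. Lists that passed no camera test held single genes that did. In ion transport, the potassium channel gene GORK had a log2 ratio of 1.39 ± 0.13 in salt (adjusted p = 0.0123; 4 of 21 genes higher, 3 lower, 4 and 3 adjusted over the list alone), and NHX5, an ion exchanger gene, fell with salt in the transgenic plants by -1.52 ± 0.12 beside -1.60 in wild type. In oxidative stress, UPOX was at 2.12 ± 0.44 in salt (5 of 19 higher, 2 lower, 5 and 3 adjusted over the list alone), and AOX1A, an alternative oxidase gene, rose with salt in the transgenic plants by 2.81 ± 0.63. In the cuticle, wax and suberin list, FAR1 and CER4, of fatty alcohol synthesis, rose with salt in the transgenic plants by 2.72 ± 0.40 and 2.29 ± 0.35 and stood at 4.20 and 1.73 in wild type (8 of 30 genes higher and 3 lower in the transgenic plants). Heat shock genes had 5 of 15 higher and 1 lower, with the heat shock factor gene HSFA2 at 3.41 ± 1.12 in the transgenic plants and 2.61 in wild type.

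Jasmonate and ethylene defence genes had 1 of 7 higher and 0 lower by genotype in salt (4 higher adjusted over the list alone), with the chitinase gene CHIB at 1.99 ± 0.29. Of shoot apex and flower markers, 3 of 6 were higher and 0 lower by genotype in salt. Among these were genes whose wild-type signal in salt was above background on no array, with limits of only 1.12-fold and 1.09-fold. Root markers had 0 of 3 higher and 0 lower in limma's test of the genotype effect in salt, but 1 of 3 higher and 0 lower in control. Among clock genes, the evening genes TOC1 and ELF4 changed with salt in the transgenic plants by -0.77 ± 0.12 and 1.06 ± 0.20, beside -0.93 and 1.00 in wild type. The 10 commonly used reference genes had medians of -0.12 for genotype in control, 0.030 in salt, 0.11 for salt in wild type and 0.28 for salt in the transgenic plants. Single members were called all the same. By genotype, 1 was higher and 4 lower in control, and 3 were higher and 3 lower in salt. On the Cy5 values alone, 3 rose and 0 fell with salt in the transgenic plants. EF1A was higher by genotype in both conditions (0.77 ± 0.11 and 0.84 ± 0.11), and SAND rose with salt by 0.82 ± 0.12 in the transgenic plants, beside 0.82 in wild type.

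The genotype effect in control and the salt effect in wild type share the wild-type control sample. They correlated across genes at 0.56 with a covariance of 0.43, where simulated unchanged groups gave 0.61 and 0.16 with wild type as variable as the transgenic plants. The genotype effects in control and in salt, which share no sample, correlated at -0.19, and the salt effects in both genotypes at 0.48. Part of the first value may come from the shared sample: with the spread between the wild-type arrays the simulation gave 0.14 and a covariance of 0.0021, and wild type varied at most 0.273 times as much as the transgenic channels.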
